A study of Mus musculus with 441 samples.

How the data were processed

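The data were single-cell transcriptomes of CD4 T cells from mouse pancreatic islets, made with the full-length SMART-Seq2 protocol and sequenced with paired-end reads on an Illumina NextSeq, per the labels. Each cell was sorted by FACS after staining with a tetramer, a reagent of linked MHC class II molecules carrying a peptide that binds T cells with a matching receptor. The labels name a HIP and an Ins tetramer sort without spelling out either abbreviation. TopHat, Bowtie, RSEM 1.2.8 and the mouse build mm10 are named in the submitters' processing notes, without the role each played. The filters on genes and cells that preceded deposit are not given in the sources used here.

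The deposited expression table held natural log values for 13561 genes in 441 cells. The analysis plan written beforehand assumed TPM, the share of each transcript scaled to a total of 1000000, on a linear scale, but the exponential of each value minus 1 summed to 100000 in every cell, so the values were read as ln(TPM/10 + 1). The values were turned back into TPM, which then summed to 1000000 per cell, and all results use this TPM. The authors' deposited annotation file gave 2 other columns that were used, the name of each cell's class and the number of genes above 0. The class agreed between that file and the labels in 441 of 441 cells, and the gene number equalled the count of values above 0 in 441 of 441 cells. No pair of cells held identical values, and the highest correlation between any pair was 0.869. The clustering method behind the classes is not given in the sources used here. The classes were cut from the same expression values, so class shares are no evidence apart from the genes that define the classes. Cluster 2, annotated as activated CD4 T cells, had 3 markers of Th1 effector cells and 1 of T follicular helper cells among its 10 leading genes. The 10 leading genes of cluster 4, annotated as B cells, included none of the B cell markers fixed beforehand. Both are therefore referred to by number.

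TPM keeps no sequencing depth, so depth per cell is unknown and the number of genes detected is the only stand-in. Transcripts of the ribosomal RNA precursor Rn45s took 2.60% of TPM on average, with a range over cells of 0.188% to 44.4%. A value of 0 can be a failed capture: Gapdh was listed at 0 in 29 cells and Actb in 1. The cells were sorted singly per the labels, and no doublet caller was run. The table held no T cell receptor variable segments and no mitochondrially encoded genes, so a planned comparison of receptor segments was not run.

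The labels name no animal, so each tetramer sort counted as 1 sample. No test was made, no p-value or standard error was computed from cells, and differences have no replicate check. A gene was called detected in a cell at 1 TPM or more. Shares carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the limit set by 3 cells of the total. This limit lies below the upper end of the exact interval, at 4.92% against 5.87% for 0 of 61 cells. Intervals and limits cover counting error only and limit cells with a detected transcript, not cells expressing the gene. Means of TPM are given with the SD over cells, which is spread between cells and not replicate error. Differences between sorts are differences of mean log2(TPM + 1), HIP minus Ins, on a scale that understates changes of genes at low levels. Where many cells hold 0, these differences largely follow the share of cells detected and can far exceed the change in mean level. Ms4a4b in the dividing class, detected in 100% of HIP and 42.9% of Ins cells, differed by 5.67, but its mean TPM was 2.36 times higher in HIP. Cell names carry numbers, and blocks of 96 consecutive numbers each held cells of only 1 sort (2 HIP and 3 Ins blocks). They may correspond to plates, which the labels do not name, and were used to describe spread within a sort, not as replicates.

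The rule for named genes was fixed before the data were examined. Within clusters 0 and 2 it took genes detected in at least 25% of the cells of either sort whose mean was higher, or lower, in every HIP block than in every Ins block, and named the 8 largest differences in each direction. Receptor and immunoglobulin segments, unnamed gene models, ribosomal protein genes and mitochondrial genes were left out. In the dividing class it named the 4 largest in each direction without the block condition, because that class held 9 HIP cells. A set of core lineage genes was always named, together with the 4 members of each fixed gene list with the largest difference among members detected in 10% of the cells of either sort. Each list is given as its median difference with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these cells only. In chance orders of the 5 blocks, every HIP block lies above every Ins block in 10%, and below in another 10%. List symbols missing from the table were looked up as older symbols, which found Folr4 for Izumo1r and Cd244 for Cd244a. Genes such as Il2, Il17a, Il13 and the immunoglobulin constant genes were not among the rows and are not analysed here. Of the genes this rule named, 4 are not reported here and were left out of the counts of alternatives, though they remain members of their lists.

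Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are from GENCODE M21 on mm10, in which 12676 of the table's symbols (93.5%) were found. The comparison was checked on simulated data with 200 genes changed 8-fold in cells drawn from the real classes. The direction came out right for 97.5% of them among 2112 genes in the T follicular helper class, 91% among 2290 in cluster 2 and 87% among 5340 in the dividing class. Simulated changed lists lay above the central 95% of random lists in 100%, 100% and 85% of cases in the same order, and unchanged lists lay outside it in 1%, 0% and 5%. Unchanged lists were random genes and both simulated sorts were drawn from the pooled class, so a low share was set in advance. Neither block effects nor genes that vary together were simulated, and changes under 8-fold were not tried. The check therefore does not show how often the reported lists would reach their percentiles by chance. The alternatives tried were other pseudocounts, detection limits and filters, a minimum of 1500 genes per cell, equal weight for each block, medians over cells, single blocks, and TPM rescaled without the 100 most abundant genes. Rescaling shifted the median difference over genes by -0.01, 0.02 and 0.03 in the T follicular helper class, cluster 2 and the dividing class.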

Results

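The data set held 441 cells from mouse pancreatic islets, each sorted as a beta-cell-specific CD4 T cell by tetramer. Of these, 184 came from the HIP tetramer sort and 257 from the Ins tetramer sort. The authors' annotation divided them into 172 T follicular helper cells (cluster 0), 118 regulatory T cells or Tregs (cluster 1), 86 cells of cluster 2 annotated as activated CD4 T cells, 44 dividing CD4 T cells (cluster 3) and 21 cells of cluster 4 annotated as B cells. The series as a whole concerns how peptide loading of MHC class II shapes antigen presentation in autoimmunity, and the sorts ask which states islet T cells take when they bind different tetramers. The number of genes detected per cell was 2081 at the median, with a range of 625 to 5929. It was 2021.5 in the HIP sort and 2148 in the Ins sort, and over blocks it ranged from 1799 to 2175.5 in HIP and from 1840 to 2279 in Ins. Each sort was 1 sample, so the values below have no replicate error, and all intervals cover counting error only.

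Regulatory T cells made up much of the Ins sort and were nearly missing from the HIP sort. Foxp3, the transcription factor that defines the Treg lineage (X chromosome, 7573644 to 7595245, mm10), was detected in 133 of 236 Ins T cells (56.4%, interval 49.8% to 62.8%) and in 3 of 184 HIP T cells (1.63%, 0.338% to 4.69%). Its mean level was 337 ± 463.2 TPM (SD over cells) in Ins and 2.75 ± 24.2 TPM in HIP. Il2ra, the high-affinity interleukin 2 receptor chain, was detected in 26.7% (21.2% to 32.8%) of Ins and 4.89% (2.26% to 9.08%) of HIP T cells. Over all T cells, 2 cytokine genes lay the other way: Il21, which supports B cell help, was detected in 32.6% (25.9% to 39.9%) of HIP and 14.0% (9.82% to 19.1%) of Ins T cells, and Ifng, the type 1 effector cytokine, in 15.2% (10.4% to 21.2%) and 3.39% (1.47% to 6.57%). These shares mix classes of different size in the sorts, and within the T follicular helper class Il21 was found in 23.4% of HIP and 27.9% of Ins cells. Tbx21, which encodes the type 1 factor T-bet, was found in 10.9% of HIP (6.77% to 16.3%) and 24.6% of Ins T cells (19.2% to 30.6%). In cluster 2 it was found in 10 of 61 HIP (16.4%, 8.15% to 28.1%) and 2 of 25 Ins cells (8.00%, 0.984% to 26.0%), with overlapping intervals. Icos, a costimulatory receptor of follicular helper cells and Tregs, was found in 53.8% (46.3% to 61.2%) and 67.8% (61.4% to 73.7%), with 48.9% and 58.3% in the HIP and 80.0%, 69.6% and 56.3% in the Ins blocks. Intervals of the sorts overlapped for Ctla4 (53.3% of HIP and 66.5% of Ins T cells), Cxcr3 (44.0% and 56.4%), Bcl6 (31.5% and 20.3%), Pdcd1 (62.0% and 51.3%), Cxcr5 (27.7% and 23.7%) and Mki67 (8.70% and 13.6%). Cd4 was detected in 85.9% of HIP and 85.6% of Ins T cells, and Cd3e in 176 of 184 and 230 of 236.

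**Figure D1:**
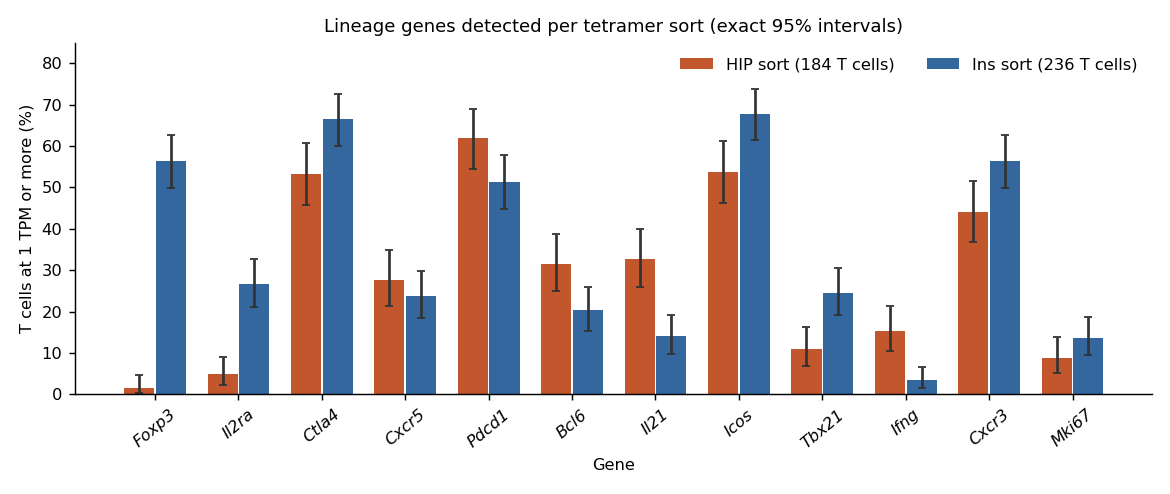
Share of T cells of the HIP sort (184 cells) and the Ins sort (236 cells, without cluster 4) with each lineage gene at 1 TPM or more, with exact 95% intervals over cells. Foxp3 was found in 1.63% of HIP and 56.4% of Ins T cells, while Il21 and Ifng were found more often in HIP.

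The annotated classes showed the same contrast. Tregs were 115 of 257 Ins cells (44.7%, 38.6% to 51.1%) and 3 of 184 HIP cells (1.63%, 0.338% to 4.69%). T follicular helper cells were 60.3% of the HIP sort (52.9% to 67.4%) and 23.7% of the Ins sort (18.7% to 29.4%), and cluster 2 was 33.2% (26.4% to 40.5%) and 9.73% (6.39% to 14.0%). Dividing cells were 4.89% of HIP (2.26% to 9.08%) and 13.6% of Ins cells (9.67% to 18.4%). Cluster 4 was 8.17% of Ins cells (5.13% to 12.2%) and 0 of 184 HIP cells, which allows a share of up to 1.63% (1.98% by the exact interval). The Treg share was 0 of 88 and 3 of 96 cells in the HIP blocks and 43.1%, 43.0% and 47.8% in the Ins blocks. No block held cells of both sorts, so a difference between blocks and a difference between sorts cannot be told apart.

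**Figure D2:**
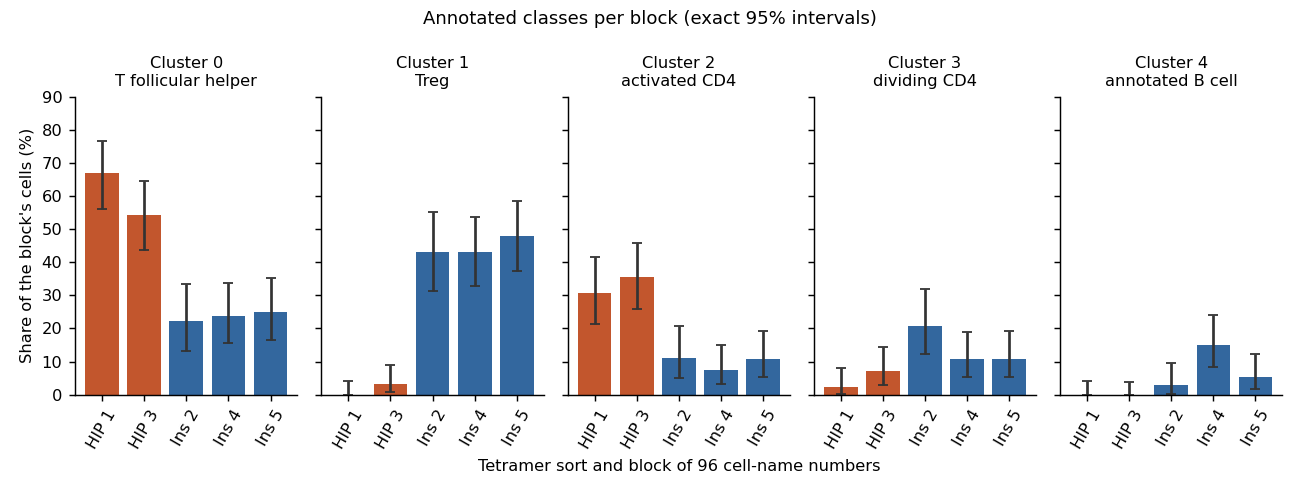
Share of cells in each annotated class for the 2 HIP and 3 Ins blocks of 96 consecutive cell-name numbers, with exact 95% intervals over cells. Treg shares lay at 3.13% or below in HIP blocks and at 43.0% or above in Ins blocks, and the T follicular helper and cluster 2 shares were higher in every HIP block.

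Within the T follicular helper class, HIP cells (111) held more transcripts of immediate-early and stress response genes than Ins cells (61). Dusp1, a phosphatase induced by stress and mitogens (chromosome 17, 26505590 to 26562128), was detected in 46.8% (37.3% to 56.6%) of HIP and 11.5% (4.74% to 22.2%) of Ins cells, with a difference of 3.81 on the log2 scale. Ppp1r15a, which restores translation during the integrated stress response, was found in 36.9% (28.0% to 46.6%) and 1.64% (0.0415% to 8.80%), a difference of 3.50. The AP-1 members Junb (2372 ± 3104 TPM in HIP and 429 ± 588 in Ins, difference 3.35) and Fos (25.2% and 1.64% of cells, difference 2.15) also lay higher. Of the fixed stress and dissociation list, 8 of 10 detected members were higher in HIP, 5 of them in every HIP block, and its median difference of 0.73 stood at percentile 99.99 of random lists. Other genes higher in HIP included Anxa2 (difference 2.80), the class I gene H2-Q8 (2.45) and the signalling adaptor Sh2d1a that follicular helper cells need to pair with B cells (2.12). H2-Q8 belongs to a family of near-identical genes among which reads can be shared, so its value is uncertain.

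Genes lower in HIP than in Ins follicular helper cells included inhibitory and Treg-associated receptors. Lag3, a receptor that restrains T cell activation, was detected in 53.2% (43.4% to 62.7%) of HIP and 78.7% (66.3% to 88.1%) of Ins cells, with a difference of -2.01. Nt5e, the ectoenzyme CD73, was found in 25.2% (17.5% to 34.4%) and 47.5% (34.6% to 60.7%), and Tnfrsf18, the receptor GITR carried by Tregs, in 27.9% (19.8% to 37.2%) and 47.5% (34.6% to 60.7%), with mean levels of 372 ± 731 and 660.1 ± 960.2 TPM for Tnfrsf18. The signalling adaptor Lax1 (-2.54), the chaperonin subunit Cct5 (-2.45), the protein folding enzyme Pdia3 (-2.27), the interferon regulatory factor Irf2 (-2.04) and the glutaredoxin Glrx (-1.98) completed the genes named on that side. Of the Treg markers, 7 of 10 were lower in HIP, 4 of them in every HIP block (median difference -0.76, percentile 0.01), with Capg (-1.18) and Foxp3 (1.80% of HIP and 13.1% of Ins cells) among them, while Ctla4 (1.17) was higher. Naive and central memory genes (7 of 9 lower, 0 of them in every HIP block, median -0.67, percentile 0.06), among them the lymph node homing receptor Ccr7 (-1.14) and the interleukin 7 receptor Il7r (-0.78), and interferon response genes (6 of 11 lower, 1 of them in every HIP block, median -0.60, percentile 0.18), with Igtp (-1.57), had medians below 0. Of 18 fixed Th1 effector markers, 6 were detected in 10% of the cells of either sort. All 6 were higher in HIP, 3 of them in every HIP block (median 0.62, percentile 99.8), with Bhlhe40 (1.46) and Stat4 (0.86). Tnf (0.73) passed that filter through the HIP cells only (12.6% of HIP and 3.28% of Ins cells). Of the markers under it, Tbx21 was lower in HIP (-0.22, 7.21% and 9.84%) and Ifng higher (0.87). The inhibitory receptor list had a median of 0.28 (percentile 97.9) and a mean of -0.11, since 8 of 12 members were higher while Lag3, Nt5e and Folr4 (-1.28) lay far lower. Ifng was found in 11 of 111 HIP cells (9.91%, 5.05% to 17.0%) and 0 of 61 Ins cells, with overlapping exact intervals (up to 5.87% in Ins). The limit set by 3 cells (4.92%) lies just under the HIP interval, so the overlap depends on the limit used. The follicular helper markers themselves split evenly, 8 higher and 8 lower (median 0.04, percentile 77.4), and Cxcr5 (40.5% and 45.9%) and Pdcd1 (62.2% and 55.7%) had overlapping intervals. The largest difference of any gene was 2.99 between both HIP blocks and 3.81 between the sorts, while Ins blocks of 16 to 23 cells differed by up to 5.48. The eighth largest was 2.53 between the HIP blocks and 2.27 between the sorts, and the median absolute difference was 0.50 and 0.39. Only Dusp1, Ppp1r15a and Junb exceeded 2.99, so the other named differences were smaller than the largest of any gene between the HIP blocks. That comparison is of sizes over all genes, not of each gene with its own blocks. The genes named by size lay apart in every block by the rule that named them. Dusp1 kept mean log2 levels of 0.81 to 1.17 in Ins and 4.61 to 4.81 in HIP blocks. Without a detection filter the Treg marker median was -0.10.

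**Figure D3:**
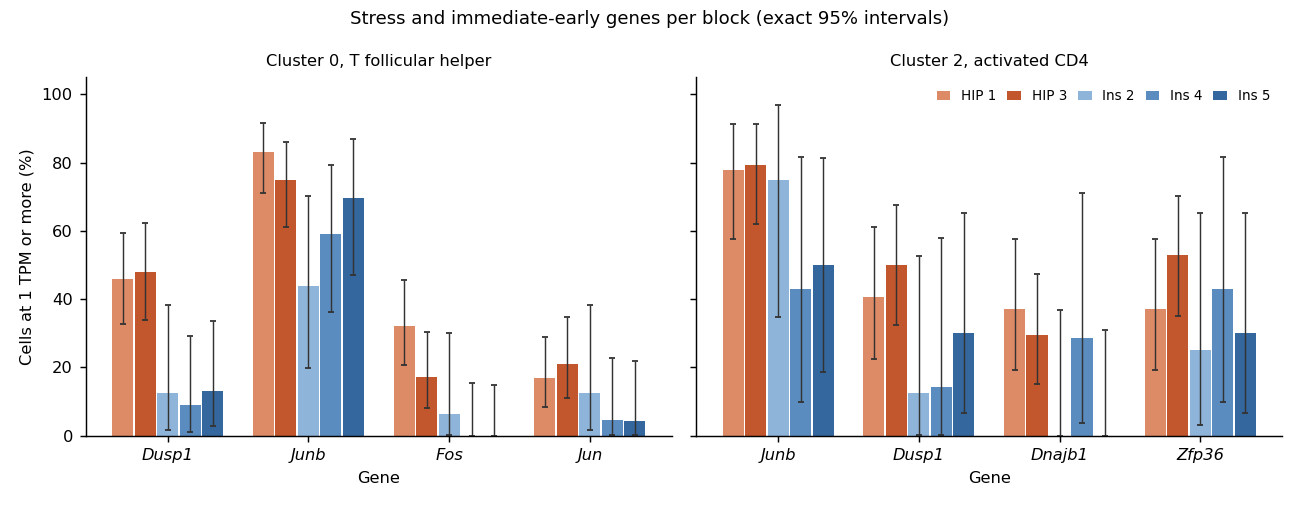
Share of cells with the 4 stress list members named in cluster 0 (left) and cluster 2 (right) at 1 TPM or more, per block of 96 cell-name numbers, with exact 95% intervals over cells. In cluster 0, Dusp1 was found in 45.8% and 48.1% of HIP cells and in 9.09% to 13.0% of Ins cells per block, while intervals in cluster 2 are wide because Ins blocks held 7 to 10 cells.

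In cluster 2, annotated as activated CD4 T cells, Junb and Dusp1 again lay higher in the 61 HIP cells than in the 25 Ins cells. Junb differed by 3.46 (1759 ± 2136 TPM in HIP and 583 ± 1052 in Ins) and Dusp1 by 3.20 (45.9%, 33.1% to 59.1%, and 20.0%, 6.83% to 40.7%). Rgs1, which dampens chemokine receptor signalling, differed by 3.22, with 2195 ± 2926 TPM in HIP and 355 ± 499 TPM in Ins. The stress and dissociation list had 8 of 10 members higher in HIP, 7 of them in every HIP block (median 1.18, percentile 100), with Dnajb1 (2.11) and Zfp36 (2.01). Other genes named higher in HIP were the kinase Csnk1a1 (3.24), the proteasome subunit Psmb3 (3.21), Fcrl1 (2.91), Lamtor5 of the complex that anchors mTORC1 to lysosomes (2.81) and Esyt1 (2.80). Those lower in HIP were the RNA polymerase subunits Polr2h (-3.13) and Polr2j (-2.19), Lpxn (-2.86), Gimap7 (-2.51), Ccng1 (-2.49), Daxx (-2.33), the phosphatase Ptpn6 that limits receptor signalling (-2.28) and Faah (-2.18).

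In cluster 2, Il21, Il10 and Ifng were each detected in more HIP than Ins cells, with overlapping intervals. Il21 was found in 45.9% of HIP (33.1% to 59.1%) and 32.0% of Ins cells (14.9% to 53.5%), Il10, an inhibitory cytokine, in 34.4% (22.7% to 47.7%) and 20.0% (6.83% to 40.7%), and Ifng in 24.6% (14.5% to 37.3%) and 8.00% (0.984% to 26.0%). At least 1 of these 3 was found in 70.5% of HIP (57.4% to 81.5%) and 48.0% of Ins cells (27.8% to 68.7%). Foxp3 was found in 0 of 61 HIP cells, which allows a share of up to 4.92% (5.87% by the exact interval). It was found in 4 of 25 Ins cells (16.0%, 4.54% to 36.1%). All 21 HIP cells with Il10 therefore lacked detected Foxp3. Among fixed lists, oxidative phosphorylation genes were higher in HIP (10 of 16, 3 of them in every HIP block, median 0.81, percentile 98.7), with Atp5o (2.41) and Uqcrq (1.82), and naive and central memory genes lower (4 of 6, 1 of them in every HIP block, median -0.64, percentile 0.910), with Lef1 (-1.28) and S1pr1 (-1.23). The cytokine list median was 0.66 (percentile 96.9) while its mean was 0.09, since Ltb (-2.18) and Lta (-1.43) lay lower in HIP. With 25 Ins cells, blocks of the Ins sort differed from each other by up to 8.47 for single genes, more than any difference between the sorts (3.46), so the order of named genes is imprecise. Without a detection filter the stress list median was 0.47. Genes detected in this cluster were 2075 at the median in HIP and 1862 in Ins cells, the opposite order to the whole sorts.

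Dividing cells carried different lineage genes in the sorts. Foxp3 was detected in 27 of 35 Ins dividing cells (77.1%, 59.9% to 89.6%), close to the Treg class of the same sort (81.7%, 73.5% to 88.3%) and above its T follicular helper class (13.1%, 5.84% to 24.2%). It was found in 0 of 9 HIP dividing cells, which allows a share of up to 33.3% (33.6% by the exact interval). Il21 was found in 6 of 9 HIP (66.7%, 29.9% to 92.5%) and 5 of 35 Ins dividing cells (14.3%, 4.81% to 30.3%), with intervals that just overlap. Cd27, a costimulatory receptor, was found in 2 of 9 HIP and 33 of 35 Ins dividing cells (94.3%, 80.8% to 99.3%), with a difference of -6.24. Tbx21 was found in 51.4% (34.0% to 68.6%) and Il2ra in 51.4% of Ins dividing cells, each in 22.2% (2.81% to 60.0%) of HIP dividing cells, with overlapping intervals, and Pdcd1 was found in 77.8% of HIP and 71.4% of Ins dividing cells and Cxcr5 in 33.3% and 37.1%.

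All 14 detected Treg markers were lower in the HIP than in the Ins dividing cells, 9 of them in every HIP block (median -1.95, percentile 0). They included Foxp3, the costimulatory receptor Tnfrsf9 (-3.22), Ikzf2, which encodes Helios (-2.70), and Ikzf4 (-2.40). Cst3 (-3.31), Cd74 (-1.995) and Cd68 (-0.89), markers of other cell types, were also lower in every HIP block. Ifngr1, a chain of the interferon gamma receptor, differed by -4.66 and the acyltransferase Agpat4, listed at 0 in all HIP dividing cells, was found in 19 of 35 Ins dividing cells (54.3%, 36.6% to 71.2%). Genes higher in HIP were Ms4a4b (5.67), the spindle protein gene Haus4 (4.90), the spliceosome gene Snrnp25 (4.68) and Mphosph6 (4.68). Glycolysis genes were higher in HIP for 14 of 16 members, 8 of them in every HIP block (median 0.98, percentile 99.99), with the glucose transporter Slc2a1 (2.42) and the hexokinase Hk1 (2.41). Cell division markers were higher for 18 of 20, 5 of them in every HIP block (median 0.84, percentile 99.5). Ccnb1 (2.81) and Kif11 (2.21) differed most but were not higher in every HIP block. The cytokine list was higher for 7 of 11, 2 of them in every HIP block (median 0.95, percentile 99.9), with Il21 (2.84) and Cd40lg, the ligand that licenses B cells (1.81), higher and Il10 (-2.34) lower. Antigen receptor signalling genes were lower for 9 of 13, 3 of them in every HIP block (median -0.87, percentile 0.385), with Irf8 (-2.64) and Nr4a1 (-1.96). Inhibitory receptors were lower for 8 of 14, 3 of them in every HIP block (median -0.51, percentile 0.73), with Folr4 (-3.54), Rgs16 (-2.48) and Lag3 (-2.18). Adhesion and chemokine receptors were lower for 11 of 17, 2 of them in every HIP block (median -0.43, percentile 2.14), with Ccr2 (-2.16), but this median was 0.48 with equal weight per block. HIP dividing cells numbered 2 and 7 in their blocks and differed from each other by up to 10.7 for single genes, above the 6.24 between the sorts, and the cytokine median was -0.21 without a detection filter. Genes detected were 3992 at the median in HIP and 3610 in Ins dividing cells. Foxp3 was found in 77.1% of Ins and 0 of 9 HIP dividing cells, so this class compares cells of different lineage make-up. The gene and list differences in it cannot be told apart from that difference in make-up.

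Transcripts of other cell types were detected in both sorts. The beta cell hormone gene Ins2 was found in 17 of 184 HIP T cells (9.24%) and 27 of 236 Ins T cells (11.4%), with a highest level of 9361 TPM in HIP and 4217 TPM in Ins. In the T follicular helper class it was higher in every HIP block, with overlapping intervals (10.8% of HIP, 5.71% to 18.1%, and 4.92% of Ins cells, 1.03% to 13.7%). In the dividing class it was found in 0 of 9 HIP and 8 of 35 Ins cells. The glucagon gene Gcg was found in 2.17% of HIP and 1.27% of Ins T cells, the acinar enzyme gene Clps in 4.89% and 5.51%, and the B cell receptor gene Cd79a in 0.543% and 1.69%. Lyz2, C1qb and Fcer1g of the myeloid list were found in at most 1 cell of a sort, while Cd68 was found in 7.07% of HIP and 6.78% of Ins T cells and Cst3, on the same list, in 49.5% and 69.1%. Pecam1 of the endothelial list was found in 17.4% (12.2% to 23.7%) and 8.05% (4.92% to 12.3%), and Cdh5 of that list in at most 1 cell of a sort. Cluster 4, annotated as B cells, held transcripts of antibody-secreting cells, with Sdc1 in 20 of 21 cells (95.2%, 76.2% to 99.9%) and Xbp1 in 21 of 21. Its cells had Cd79a in 19 of 21 (90.5%, 69.6% to 98.8%), Cd3e in 1 of 21 and Cd4 in 0 of 21, which allows a share of up to 14.3%. The joining chain gene Igj took 12.7% ± 7.88 of all TPM in these cells, with a range of 3.01% to 32.1%, and averaged 0.941 ± 11.4 TPM in T cells.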

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

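The test of depth for the stress list in cluster 0 and the test of antigen receptor signalling were planned before their results were seen, and the other tests in this part were chosen afterwards, as were 2 demands on both planned tests, namely that a bound hold with each block left out and that at least 5 genes be detected. As first written, the test of antigen receptor signalling counted against that signalling, on the genes that passed the filter of 10% of cells. Of 136 named genes, 5 pointed in opposite directions in clusters 0 and 2, with every HIP block above every Ins block in the one and below in the other. Among all 5125 genes detected in 10% of the cells of a sort in both clusters this held for 1.31%, where independent chance orders of the blocks give 2%, so chance could account for such genes. Genes lying apart in every block in the same direction in both clusters made up 1.66%, also under the 2% of chance orders. Lamtor5 (-0.78 and 2.81) and Psmb3 (-1.87 and 3.21) had gaps of -3.59 and -5.08 on the log2 scale, and Stat4 (0.86 and -1.22) of 2.08. Bcl6 (1.05 and -0.47, gap 1.53) was found in 4.92% of HIP and 12.0% of Ins cells of cluster 2, and Top2a (0.39 and -0.95, gap 1.35) in 5.41% and 0% in cluster 0, so both rest on few cells.

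The near absence of Foxp3 from the HIP sort was weighed against technical causes. Among T cells with at least 1500 and fewer than 2500 genes detected, Foxp3 was found in 54.0% of Ins and 1.74% of HIP cells, a gap of 52.3 percentage points, which argues against fewer detected genes as the cause. The lowest Ins block exceeded the highest HIP block by 45.0 points (47.1% and 2.08%), which argues against a single block carrying the difference. A step shared by all blocks of a sort stays open, because 0 blocks held cells of both sorts, and the labels name no animals. A difference in the cells that bind each tetramer may account for the pattern and was not tested apart from such a step.

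Immediate-early and stress genes were higher in HIP cells of clusters 0 and 2. With cells of at least 1500 genes, the list median in cluster 0 was 0.90 against 0.73 in all cells and 0.69 to 1.59 with each block left out, above the planned bound of 0.5, which argues against detection depth as the whole cause there. In cluster 2 it was 1.30 against 1.18 and did not shrink, and 0.79 to 2.11 with each block left out, all above the 0.59 under which depth was predicted to bring it, but at the lowest just under the bound of 0.8, so depth is not excluded there by that bound. Stronger antigen receptor signalling could raise such genes. The 3 members of the Nr4a and Egr families that passed the detection filter in cluster 0 had a median of -0.42. They went both ways (Nr4a1 0.79, Egr1 -0.42, Egr2 -0.48) and were found in at most 18.0% of cells of a sort. Their median was -0.61 to 0.089 with each block left out. Of the members under the filter, Nr4a2 (0.50) and Nr4a3 (0.38) were higher in HIP and Egr3 (-0.027) was lower. Nr4a2 and Nr4a3 were each found in 7.21% of HIP and 0% of Ins cells. The negative median therefore depends on the filter, and the test decides nothing. A difference in tissue handling or time before lysis could also raise the stress genes. In the dividing class the stress list median was -0.044, with 9 HIP cells too few to exclude such a difference. Signalling, handling and a biological difference between the sorts cannot be told apart here.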

How the results depend on the processing

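No paired analysis was possible because cell numbers only name cells and each sort is 1 sample, which also left no replicate to leave out. Limits of fewer than 2500 and of at least 2500 genes and the Rn45s limit were chosen after seeing the data; the comparison of receptor segments was not run because the table held none. Foxp3 in T cells ranged from 1.61% to 1.94% in HIP and from 54.0% to 59.3% in Ins over 6 alternatives. The Treg share was 0% in HIP block 1 alone and 51.8% in Ins without the dividing class. In Ins, dividing cells were 20.8% in block 2 alone, and cluster 4 was 2.78% in block 2 and 15.1% in block 4. Requiring detection in 50% of cells kept 8 of the genes named by size in cluster 0 and 8 in cluster 2. Without a detection filter, list medians were -0.10 (Treg, cluster 0), 0.47 (stress, cluster 2) and, reversed, -0.21 (cytokines, dividing). The Treg median in dividing cells was -2.68 with a pseudocount of 0.1 and -1.07 with 10. The inhibitory list in cluster 0 reversed as a mean (-0.11). With medians over cells, Cd3g in cluster 2 (-0.055) and Cycs in dividing cells (-0.11) reversed. With equal weight per block, Ccr8 (0.48), Igtp (0.42), Cd8b1 (-0.019), Sdha (-0.32) and the adhesion list (0.48) reversed in dividing cells, of which 2 and 7 came from the HIP blocks. The causes were not tested. Across all alternatives, values of named genes moved by more than 0.58 on the log2 scale (1.5 times for a count) in 102, 147 and 196 cases. They moved by less in 396, 386 and 310 cases, in cluster 0, cluster 2 and dividing cells in that order. Reversals were counted apart. For a gene, a change of sign was called a reversal only where its main difference was at least 0.58. Sign changes of smaller differences are therefore within these counts and not among the reversals listed. Medians over cells alone moved 59, 71 and 63 values in the same order and left 24, 17 and 21 within the limit; Dusp1, Ppp1r15a and Fos in cluster 0 then differed by 0, because fewer than 50% of the cells of either sort held them. Depth per cell is unknown, so undetected transcripts limit every share.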

Other observations

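The test in the last paragraph of this part was chosen after its result was seen. Single effector genes were detected in part of the Ins Tregs, without a comparison to other classes. Tbx21, which encodes T-bet, was detected in 27.8% (19.9% to 37.0%) of the 115 Ins Tregs, the chemokine receptor Cxcr3 in 61.7% (52.2% to 70.6%), the chemokine Ccl5 in 34.8% (26.1% to 44.2%), the cytotoxic protease Gzmb in 18.3% (11.7% to 26.5%) and Il10 in 45.2% (35.9% to 54.8%). Ifng was found in 2.61% (0.541% to 7.43%) of them and Il21 in 2.61%. Areg, a tissue repair factor of Tregs, was found in 4.35% (1.43% to 9.86%). Lag3 was found in 98.3% of Ins Tregs (4215 ± 3090 TPM) and 95.1% of HIP cluster 2 cells (3757 ± 2802 TPM). Among follicular helper cells it was found in 53.2% of HIP (546 ± 865 TPM) and 78.7% of Ins cells (892 ± 1017 TPM).

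Foxp3 was also found outside the Treg and dividing classes, in 12 of 86 Ins cells (14.0%, 7.42% to 23.1%) and 2 of 172 HIP cells (1.16%, 0.141% to 4.14%). Il10 in cluster 2 was found without Foxp3 in 21 of 61 HIP cells (34.4%, 22.7% to 47.7%) and 3 of 25 Ins cells (12.0%, 2.55% to 31.2%). Among HIP cluster 2 cells, Il10 was found in 12 of 28 cells with Il21 and in 9 of 33 without, with overlapping intervals. Cd8b1, which encodes a chain of the CD8 coreceptor, was detected without Cd8a in 33.2% of HIP (26.4% to 40.5%) and 20.3% of Ins T cells (15.4% to 26.0%), at medians of 2.74 and 2.97 TPM where detected. These Cd8b1 values were looked at after the table was seen, and they lie close to the detection limit.

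The following 3 fixed lists lay inside the central 95% of random lists in clusters 0 and 2. Antigen receptor signalling had medians of 0.15 and 0.44 (percentiles 91.0 and 91.7), glycolysis -0.10 and 0.17 (55.0 and 51.4), and survival and apoptosis -0.15 and 0.25 (37.6 and 78.5). In the dividing class, Th1 effector markers had a median of -0.35 (percentile 4.36) and interferon response genes of 0.18 (49.8), and naive and central memory genes a median of -0.01 beside a mean of 0.41. Xist was found in 59.5% of HIP and 55.7% of Ins follicular helper cells.

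Foxp3 was found in a larger share of dividing than of other Ins T cells, 77.1% against 52.7%, a gap of 24.4 percentage points. Dividing cells had more genes detected, which could raise detection. Among cells with at least 2500 genes the shares were 78.8% (61.1% to 91.0%) and 63.6% (45.1% to 79.6%), a gap of 15.2 points with overlapping intervals, so detection depth and a higher division rate of Tregs cannot be told apart.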
